A study of Tetrahymena thermophila with 2 samples.

How the data were processed

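Whole-cell RNA was sequenced from 2 mating cultures of the ciliate Tetrahymena thermophila. One was a cross between the wild-type strains B2086 and CU428 and the other a cross between strains of that background whose CYC2 gene had been knocked out in the somatic nucleus. Per the labels' protocols, RNA was taken from conjugating cells, poly(A) RNA was selected with oligo-dT beads, and libraries were made with a NEBNext Ultra RNA kit after fragmentation and random priming. The labels give 1 library for each cross and do not say how long after mixing the cells were taken.

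The authors deposited a table of FPKM values (fragments scaled to transcript length and to the number of mapped fragments of the library) for 26996 genes, with 1 column for each cross. They also deposited a table of 1260 genes from their own comparison of the crosses. Per the submitters' processing notes, the tools used were cutadapt, Bowtie2 2.1.0, TopHat2 2.1.1, Cufflinks 2.2.1, RSEM 1.2.27 and DESeq 1.24.0. The notes as used here assign these tools no role, so which of them produced the FPKM values or the comparison is not given in the sources used here, and neither are the genome build and the annotation. In the deposited comparison table, the fold is a linear ratio and its log2 value is that ratio on a log scale. Both were checked against the FPKM columns and equal the wild-type value divided by the knockout value, so a gene the deposited table calls up was higher in the wild type. The deposited p-values are unadjusted and adjusted, and the unadjusted ones are whole multiples of 5e-05. The FPKM columns of both deposited files were identical for all 1260 shared genes.

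All 26996 gene identifiers matched a locus tag of the RefSeq assembly JCVI-TTA1-2.2. That table gave 0 symbols other than the locus tags themselves, and the deposited files do not pair identifiers with names. The 22 gene lists fixed before the data were examined (cyclins, meiotic recombination, tubulins, small RNA pathway and others) were built from symbols and product names, so 0 of them could be matched and no list result is given. The rule for named genes fixed at the same time asked for CYC2, for genes with informative product names, and for the largest changes whatever their name. The part that needs product names could not be applied. CYC2, which the labels identify as TTHERM_00079530, is named with the 2 most negative and the 2 most positive folds among the other genes. The rule asked for more rises than these 2, so naming only 2 was a departure from it. The reference table served for gene order and gene length. Coordinates are printed as the deposited comparison table gives them, with starts counted from 1.

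Folds were computed as log2((knockout FPKM + 1)/(wild-type FPKM + 1)). The pseudocount of 1 understates the change of weakly expressed genes. Genes entered the counts where the higher library had an FPKM of at least 1, and were counted by size at 2-fold, 4-fold and 8-fold. With 1 library per cross there is no replicate error, so no p-value was computed, and a count states how these 2 libraries differ, not how the genotypes differ.

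Depth was read from the low values. Among 285 genes longer than 1500 bp with very low values in both libraries, 92.3% had a knockout to wild-type ratio within 0.03 (log2) of a ratio of whole numbers up to 6, after a common factor. That factor, the value of 1 fragment in the knockout over that in the wild type, was 0.939. By the authors' normalization this puts the knockout library at 1.06 times the depth of the wild-type library. The factor was the median over 93 of these genes, taken as having equal counts because their knockout values lay slightly below the wild-type ones. That choice confined it to a narrow range, so it is an estimate within that range only. A coarser estimate took the median of FPKM times gene length over genes in the range of a single fragment, 45 to 105. It was 77.1 over 260 genes in the knockout and 88.8 over 110 genes in the wild type, a depth ratio of 1.15, but the genes differ between the libraries and the lengths include introns. By these medians a 2000 bp gene with 1 fragment would be listed near 0.0385 FPKM in the knockout and 0.0444 in the wild type. The total number of fragments of each library is not given in the sources used here. Intervals cover counting error only.

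The counting by fold was run on simulated data for this comparison. A knockout library was drawn with Poisson fragment noise around the wild-type levels, and the wild-type library itself was left without noise. Folds were planted only in genes at 10 FPKM or more in the wild type. At 18915 genes, 100% of 100 genes raised 4-fold and 100% of 100 genes lowered 4-fold were recovered at 2-fold or more, and 0% of the unchanged genes passed 2-fold. Recovery of 4-fold changes planted at 10 FPKM or more says nothing about weaker genes. With no noise in the wild-type library, the 0% is not an error rate for the deposited libraries. Whether the drawn noise matched that of short gene models was not tested, so the simulation cannot show how counting behaves for them. Culture and library preparation add variation that this simulation leaves out.

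Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter or an FPKM minimum of 5, and 3 other scalings. The scalings were TPM, a median log2 ratio of 0, and a mean log ratio trimmed by 30% of the ratios and 5% of the levels. Alternatives chosen after seeing the data left out gene models under 500 bp, left out genes listed at 0 in either library, or removed a running median over 1001 genes ordered by length. The gene list alternatives were not run. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.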

Results

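The study examined how loss of the cyclin gene CYC2 alters transcription in mating Tetrahymena thermophila, a ciliate that carries a germline micronucleus and a somatic macronucleus in 1 cell. Per the series title, the cyclin is needed for the meiotic micronucleus to elongate. Cyclins are the regulatory partners of cyclin-dependent kinases, and micronuclear elongation is the stretching of the germline nucleus in meiotic prophase. Messenger RNA was profiled once in a cross of wild-type strains and once in a cross of somatic CYC2 knockout strains, so each group holds 1 library and no value below has a replicate error. Of 26996 annotated genes, 18679 had an FPKM of at least 1 in the wild-type cross and 17911 in the knockout cross. The wild-type library listed 2941 genes at exactly 0 and the knockout library 4232, with 2534 at 0 in both. The FPKM values summed to 1261745 in the wild type and to 1105995.5 in the knockout. By the value of a single fragment within the same genes, the knockout library was estimated at 1.06 times the depth of the wild-type library. The choice of genes confined that estimate to a narrow range. A coarser estimate over different genes in each library gave 1.15 times.

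CYC2 (TTHERM_00079530), the gene that was deleted, was among the abundant transcripts of the wild-type cross, at 1582 FPKM, and was nearly absent from the knockout cross, at 0.0275 FPKM. The knockout value multiplied by the length of the gene was 68.3, against a median of 77.1 over the 260 knockout genes in the range of a single fragment, so it corresponds to about 1 fragment. The wild-type level was 57446 times the knockout level, and a count of 1 fragment gives that ratio a 95% exact Poisson interval of 10310 to 2268997. On the log2(FPKM + 1) scale CYC2 was lower by 10.59 (log2 fold -10.59), the largest difference of any gene in either direction. The value goes with the label of each library.

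Genes next to CYC2 on its scaffold were also measured. The neighbour on the side of lower coordinates stood at 348.7 FPKM in the wild type and 101.6 in the knockout, a log2 fold of -1.77. The nearest gene on the other side stood at 4.42 and 1.00 FPKM (log2 fold -1.44), and the gene 3 positions away on that side at 25.1 and 6.35 FPKM (log2 fold -1.83). The genes 2 and 3 positions away on the side of lower coordinates differed the other way, with 10.1 FPKM in the wild type against 21.9 in the knockout, and 57.1 against 67.3.

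**Figure D1:**
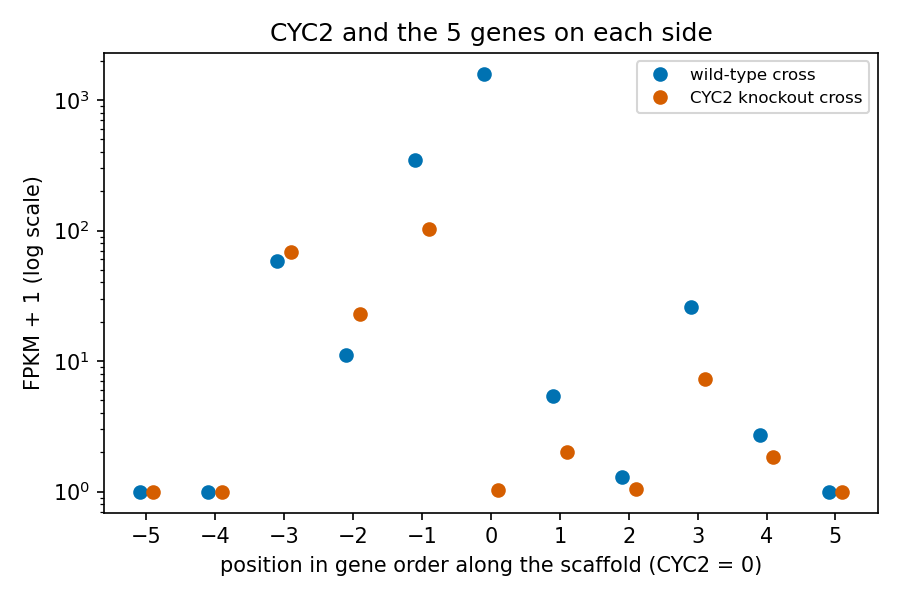
FPKM + 1 (log scale) of CYC2, at position 0, and of the 5 genes on each side in gene order along its scaffold, with 1 point per library (blue, wild-type cross; orange, CYC2 knockout cross). CYC2 stands at 1582 and 0.0275 FPKM, while the neighbour at position -1 stands at 348.7 and 101.6 FPKM.

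The main comparison asked which transcripts differed between the knockout and the wild-type cross. Deep differences were mostly losses in the knockout. Of 19328 genes with an FPKM of at least 1 in the higher library, 884 were at least 4-fold lower in the knockout and 277 at least 4-fold higher. At 8-fold the counts were 305 lower and 31 higher. At 2-fold the directions were nearly balanced, with 2967 genes lower and 2707 higher, and 70.6% of the genes lay within 2-fold. The share of higher genes among the 2-fold calls was 47.7% as deposited. It was 60.3% after rescaling both libraries to TPM (3510 higher, 2313 lower), 39.4% with the median log2 ratio set to 0 (2145 higher, 3303 lower) and 49.2% with the trimmed mean of log ratios. With an FPKM minimum of 5 it was 51.4% (2482 higher, 2345 lower), so the direction of the majority at 2-fold depends on the scaling and on the filter. The scaling to TPM moved the median log2 fold of all tested genes from 0.06 to 0.21, and setting the median log2 ratio to 0 moved it to -0.05. At 4-fold the lower genes outnumbered the higher ones under each of the 3 other scalings, by 1.81 to 4.75 times. The libraries were also correlated over all 26996 genes, which include 2534 at 0 in both and are not independent replicates. Pearson r was 0.922 on the log2(FPKM + 1) scale and Spearman rho was 0.929.

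**Figure D2:**
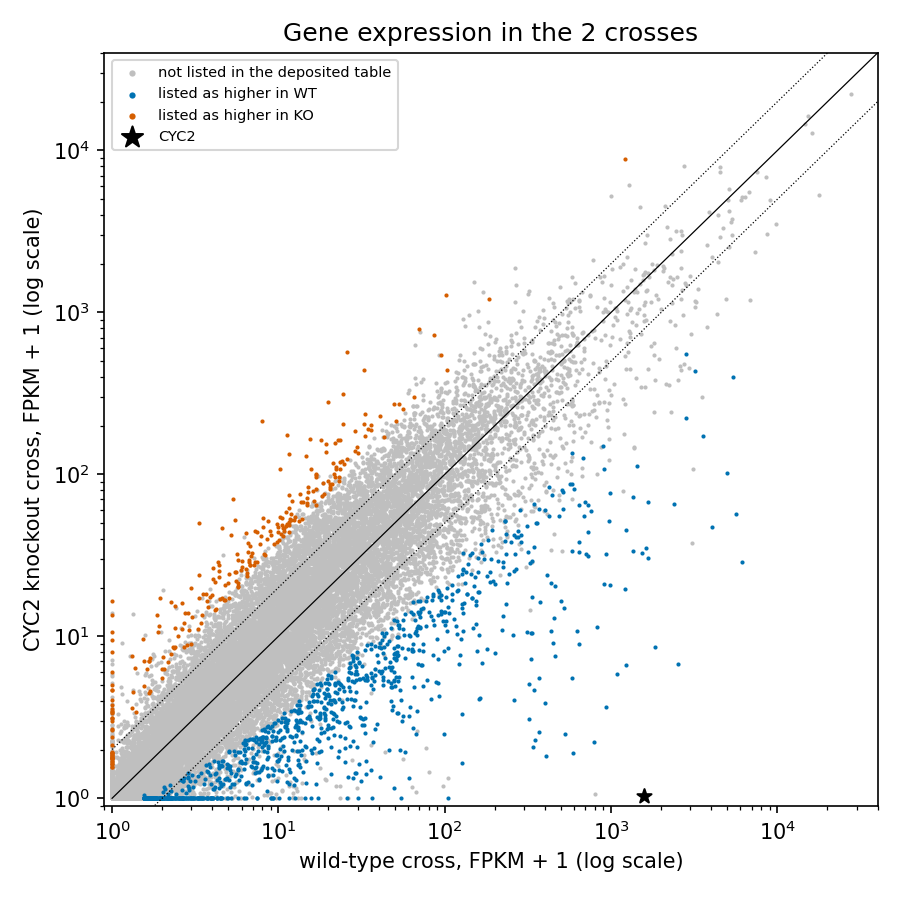
FPKM + 1 of each gene in the wild-type cross (x axis) and the CYC2 knockout cross (y axis), both on log scales, with 1 library each. The solid line marks equality and the dotted lines 2-fold differences. Blue and orange points are the 998 and 262 genes that the authors' deposited table lists as higher in the wild type and in the knockout, grey points are other genes, and the star is CYC2. The blue points reach much farther from the line than the orange ones.

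**Figure D3:**
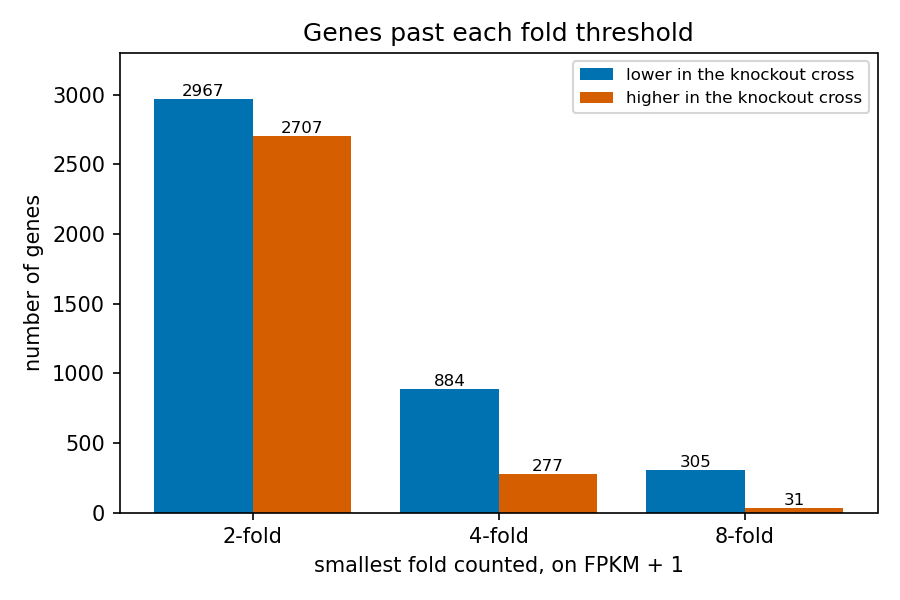
Number of genes (y axis, from 0) that were lower (blue) or higher (orange) in the knockout cross by at least 2-fold, 4-fold and 8-fold on the FPKM + 1 scale. Lower genes number 2967, 884 and 305, and higher genes 2707, 277 and 31.

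The genes that were at least 4-fold lower had a median of 48.5 FPKM in the wild-type cross and of 4.62 FPKM in the knockout. All tested genes had medians of 9.61 and 9.76 FPKM. Choosing genes by fold favours those that are high in 1 library, so the levels and shares given here partly follow from the choice. Together the lower genes held 18.6% of the wild-type FPKM sum and 2.37% of the knockout sum. The genes at least 4-fold higher had medians of 10.6 FPKM in the wild type and 55.8 FPKM in the knockout, and their share of the FPKM sum was 0.869% in the wild type and 5.86% in the knockout. A group of 97 genes stood at 10 FPKM or more in the wild type and under 1 FPKM in the knockout, CYC2 among them, with a median of 16.1 FPKM in the wild type. The opposite pattern held for 7 genes, the highest of them at 16.2 FPKM in the knockout. At a stricter limit, 50 genes had at least 100 FPKM in the wild type and under 10 FPKM in the knockout. These counts set no limit on gene length. The group of 97 includes gene models under 500 bp, and a fragment adds more FPKM to a short model than to a long one. How many of the 97 rest on few fragments was not tested, so not all of them need be losses as clear as that of CYC2.

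After CYC2, the gene with the most negative fold at a pseudocount of 1 was TTHERM_00399200. At a pseudocount of 5 its log2 fold was -7.32 and that of TTHERM_000420399, the next gene at a pseudocount of 1, was more negative, at -7.89. TTHERM_00399200 stood at 802.0 FPKM in the wild type and at 0.0632 FPKM in the knockout (log2 fold -9.56), a knockout level that also corresponds to about 1 fragment. The wild-type level was 12687 times the knockout level, with an interval of 2277 to 501116. The gene listed just before it on the scaffold was lower as well, at 458.5 FPKM in the wild type and 19.5 in the knockout, while the gene after it stood at 12.4 and 12.1 FPKM. TTHERM_000420399 lies on scaffold NW_002476250.1 from 274264 to 275228. It stood at 2532 FPKM in the wild type and 5.72 FPKM in the knockout, a log2 fold of -8.56. The most positive fold at a pseudocount of 1 was that of TTHERM_00494759, on scaffold NW_002476226.1 from 472809 to 473192, with 6.99 FPKM in the wild type and 213.0 FPKM in the knockout (log2 fold 4.74). It was followed by TTHERM_00637260, on scaffold NW_002476302.1 from 151863 to 154710, with 25.02 and 568.5 FPKM (log2 fold 4.45). At a pseudocount of 5 their order was reversed, with log2 folds of 4.18 for TTHERM_00494759 and 4.26 for TTHERM_00637260. At a pseudocount of 0.1 they ranked 19 and 31 among the positive folds, mostly behind genes listed at 0 in the wild type, and TTHERM_000420399 ranked 8 among the negative ones. The sources used here give no names for these 4 genes.

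The balance of lower and higher genes at 2-fold varied with expression level. Among the 162 genes with a mean of at least 1000 FPKM over both libraries, 51 were at least 2-fold lower in the knockout and 10 at least 2-fold higher, and the median log2 fold was -0.48. Among the 3298 genes with a mean between 30 and 100 FPKM, 517 were lower and 734 higher, with a median log2 fold of 0.26. Among the 4167 genes with a mean under 3 FPKM, 612 were lower and 204 higher. At 4-fold the lower genes outnumbered the higher ones in every class of expression, with 182 lower and 85 higher between 30 and 100 FPKM. Genes at or above 1000 FPKM numbered 185 in the wild type and 149 in the knockout, and they held 44.0% and 35.3% of the respective FPKM sums. The 10 most abundant genes held 10.7% of the sum in the wild type and 10.1% in the knockout.

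The authors' deposited table lists 1260 genes, of which 998 were higher in the wild type and 262 higher in the knockout. In the authors' deposited table the unadjusted p ran from 5e-05 to 0.04995 and the adjusted p from 0.0519 to 0.824, so 0 of the listed genes had an adjusted p under 0.05. The 20 genes at the smallest unadjusted p in the authors' deposited table were all higher in the wild type. In the authors' deposited table, genes higher in the wild type had a median of 16.8 FPKM there and 1.79 FPKM in the knockout, and genes higher in the knockout had medians of 5.50 and 29.5 FPKM. The table gives 212 genes listed at 0 in the knockout and 40 listed at 0 in the wild type, for which the fold is not finite. For TTHERM_000420399 the authors' deposited table gives an adjusted p of 0.277, for TTHERM_00494759 also 0.277, and for TTHERM_00637260 an adjusted p of 0.733. CYC2 and TTHERM_00399200 are not among the genes of that table as used here. Of the 1161 genes that differed at least 4-fold on the FPKM + 1 scale, 347 are not among the listed ones. Of the 132 that differed at least 16-fold, 21 are not, all of them lower in the knockout. The selections are unlike: the smallest finite log2 fold listed was 1.98 in absolute value, without a pseudocount. The listed genes also all had an unadjusted p under 0.05, whereas the FPKM + 1 counts use no p.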

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

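The scalings, filters, pseudocounts and extra limits on the deposited table were planned, whereas leaving out short genes, leaving out genes listed at 0 and removing the length trend were chosen after seeing the data. Of 99 alternative values, 82 stayed within a set limit of the reported value and 17 moved beyond it. The limit was 1.5 times for counts and 10 percentage points for the share of higher genes. For log2 folds it was 1.5 times on the linear fold, not on the log2 value. No log2 fold of a named gene changed sign, but that of TTHERM_00399200 moved to -12.26 with a pseudocount of 0.1 and to -7.32 with 5, and that of TTHERM_000420399 to -7.89 with 5. CYC2 ranked 1 among the negative folds at each pseudocount, and the other ranks moved. TTHERM_00399200 ranked 2 at 0.1 and at 1 and 4 at 5, and TTHERM_000420399 ranked 8 at 0.1, 3 at 1 and 2 at 5. Among the positive folds, TTHERM_00494759 ranked 19, 1 and 2 and TTHERM_00637260 ranked 31, 2 and 1 at 0.1, 1 and 5. Of the 18 and 30 genes ahead of them at 0.1, 16 and 26 were listed at 0 in the wild type. The majority at 2-fold, lower as reported, turned to higher with TPM and with an FPKM minimum of 5 (2482 higher, 2345 lower, 51.4% higher). With a pseudocount of 0.1 in place of 1, the 4-fold counts became 494 higher and 1517 lower, the 8-fold counts 115 higher and 678 lower, and the log2 fold of CYC2 -13.60. With 5, the 2-fold counts became 1631 higher and 1696 lower, the 4-fold counts 117 higher and 491 lower, the 8-fold counts 14 higher and 152 lower, and the log2 fold of CYC2 -8.30. Rescaling to TPM moved the share of higher genes among the 2-fold calls to 60.3%. Without gene models under 500 bp, 20 genes instead of 31 were at least 8-fold higher. The lower genes outnumbered the higher ones at 4-fold and at 8-fold under every setting run. The deposited table kept 893 genes higher in the wild type and 243 higher in the knockout with an added 2-fold limit on FPKM + 1, and 720 and 220 with an added minimum of 5 FPKM. No paired analysis was possible because each cross has 1 library, and for the same reason no replicate could be left out. The gene list alternatives were not run, since no list could be matched to identifiers. A single library per cross gives no replicate error. The knockout levels of CYC2 and TTHERM_00399200 correspond to about 1 fragment, so the low count limits their FPKM ratios of 57446 and 12687, while their log2 folds move with the pseudocount.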

Other observations

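The tests of gene length, of runs, of CYC2 windows against random windows and of other window sizes, and the question of stage, were chosen after their result or pattern was seen. The other tests weighed here were set before their result was seen.

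The genes that differed in each direction were of different lengths. Genes at least 4-fold higher in the knockout had a median length of 1128 bp, those at least 4-fold lower 1910 bp, and all tested genes 1874 bp. When the tested genes were split by length into 4 equal classes, the class of the longest models, from 3166 bp, held 238 genes at least 4-fold lower and 12 at least 4-fold higher. The class of the shortest models, up to 1027 bp, held 255 lower and 128 higher genes. The median log2 fold was 0.10 in the shortest class, 0.20 in the second, 0.06 in the third and -0.09 in the longest. With the running median over length removed, 945 genes were at least 4-fold lower and 214 at least 4-fold higher. The excess of deep losses therefore did not go away with that trend in the median.

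Neighbouring genes also formed runs. There were 36 runs of at least 4 adjacent genes that all passed 2-fold in 1 direction, 21 of them lower and 15 higher in the knockout, while 200 shuffled gene orders gave a median of 9 such runs and at most 22. The longest run held 8 genes that were lower in the knockout, with log2 folds from -1.11 to -2.35, and 4 of them are in the authors' deposited table. The longest run of higher genes held 7, with log2 folds from 1.54 to 2.77, and 5 of them are in the authors' deposited table. Shuffled orders gave runs of up to 7 genes in each direction.

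The first pattern was the excess of deep losses, with 884 genes at least 4-fold lower against 277 higher. A difference in scaling of the size of the 3 other scalings is argued against, because the lowest ratio of lower to higher genes under them was 1.81. The ratio fell as the knockout values were raised relative to the wild type, and larger factors were not tried. As deposited, 129 genes were at least 16-fold lower and 3 at least 16-fold higher. Sampling noise of short or weak genes is argued against too, because the 1413 genes of at least 1000 bp with at least 100 FPKM in the higher library held 221 lower and 51 higher genes, a ratio of 4.33. A difference in mating or meiotic stage between the cultures cannot be told apart from an effect of the missing cyclin, since there is 1 library per cross and the labels give no time after mixing. An effect of the CYC2 loss on transcription stays open as well and was not tested.

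The second pattern was that genes beside CYC2 were lower. The median log2 fold of the 6 expressed genes among the 5 on each side was -0.99, at percentile 1.93 of 10000 windows around random expressed genes, whose median was 0.07. Windows of 3 and of 10 genes on each side gave percentiles of 1.1 and 1.01. These percentiles were computed because the lower neighbours had been seen, so they describe the region and are no test of a local effect of the deletion, which stays open. Of the 6 genes, 2 were higher in the knockout. The other explanation weighed was that neighbours of any deeply lowered gene are lower. The 120 windows around other genes lowered at least 16-fold had a median of -0.10. A median as low as that beside CYC2 was therefore not typical of them. Of these windows, 3 were as low as the CYC2 window, a percentile of 2.50. The rule set beforehand took a percentile of 2.50 or more as going with this explanation, so the value lay exactly at the limit. The comparison of medians and the interval were not part of that rule. The exact 95% interval of the percentile, 0.519 to 7.13, is too wide to decide whether CYC2 stands apart from these windows.

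The third pattern was that adjacent genes moved together. Spearman's rho of the log2 folds was 0.129 over 15625 adjacent pairs, across genes, which are not independent, and 200 shuffled orders gave -0.022 to 0.018. It was 0.037 for genes 2 positions apart and 0.006 for genes 10 apart. Transcripts or gene models running into the next gene are argued against as the whole cause, because rho was 0.0873 over 7896 pairs with a gap over 1000 bp, above the shuffled range of -0.034 to 0.027. Tandem gene copies that share reads were not tested and stay open, and no biological explanation was tested.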
